A study of Mus musculus with 2 samples.

How the data were processed

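Single-cell RNA sequencing (10x Chromium 3′ v2) was done on innate lymphoid cells (ILCs) sorted as IL7ra+ ILC from the small intestine and the colon of C57BL/6 mice aged 8 weeks. There was 1 library per tissue, and per the labels each was made from a pool of 8 fed mice. The deposited matrices hold raw counts of unique molecular identifiers (UMIs) per gene and barcode, made with Cell Ranger 3.0.2 and the mm10 genome per the labels. Each matrix had 31053 genes and 737280 barcodes and was not filtered for cells. A second deposited table held the same counts for cells chosen by the authors by a rule that is not stated, 5490 from the small intestine and 7549 from the colon. It held 17238 genes, and 0 of its values differed from the matrices at the same barcodes and genes.

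Barcodes were called cells by 1 threshold for both libraries, 10% of the 99th percentile of the UMI totals of the 3000 largest barcodes, taking the higher library (1203 UMIs after rounding up). At least 300 genes and at most 10% mitochondrial UMIs were also required. Scrublet was run on each library with an expected doublet rate of 0.8% per 1000 cells. Its automatic threshold marked under 0.5% of the cells of each library, so by a rule fixed with the design the top-scoring cells up to the expected rate were left out instead, 259 in the small intestine and 480 in the colon. This left 5426 and 7262 cells. A total of 55 barcodes were called in both libraries, against 53.4 expected by chance.

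Cells of both libraries were clustered together without batch integration in scanpy 1.11.5, with counts scaled to 10000 UMIs per cell, 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1. Mitochondrial, ribosomal, immunoglobulin, T cell receptor, sex-linked and stress genes were kept out of the variable genes. Clusters were named from marker lists of 13 cell types fixed before the data were examined, as were the gene lists, the rule for named genes and the alternatives, except where stated. A class scored in a cluster by the mean, over its markers seen in at least 10% of the cells of some cluster, of the cluster mean over the highest cluster mean. This score was set after the data had been seen. The highest-scoring name was given if at least 3 of its markers were seen and no other class had more markers among the 10 leading genes of the cluster. Class names below mean ILC3-like, ILC2-like, ILC1/NK-like and T-cell-like clusters, and the ILC3 clusters were divided into a CCR6+ LTi-like state (lymphoid tissue inducer) and an NCR+ state by a further set of markers.

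UMIs were summed over the cells of a class divided by all UMIs of those cells and scaled to CPM. Intervals are 95% intervals, exact Poisson for a level, exact conditional binomial for a ratio and Clopper-Pearson for a share. They cover counting error only, not variation between mice or libraries, and those of levels and ratios assume no extra variation between cells. With 1 library per tissue no test was possible, and no p-value or count of changed genes is given. Where 1 library had 0 UMIs of a gene, the ratio was taken against a floor of 3 counts and is a lower bound. Named genes had at least 20 UMIs over both libraries, at least 50 CPM in the higher one and a ratio of at least 2 that stayed at least 2 after subtraction of free RNA. They were ranked by the interval bound nearest to 1, and the first 10 in each direction were taken. Mitochondrial, ribosomal, antibody, T cell receptor, hemoglobin, sex-linked and predicted genes and markers of other cell types were left out by that rule.

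For each of 23 gene lists the median log2 ratio of members with at least 20 UMIs was set against 10000 random lists of the same size, matched over 20 bins of expression. The percentile describes these libraries and is not a test of the tissues. A list was called higher in a tissue only where the order-statistic interval of its median (its middle range) excluded 0, a rule set after the data had been seen. Shares of cells with a UMI were taken after thinning each cell to 1203 UMIs, which left out 0 cells. Beside a share of 0 the limit given is 3 counts of the cells, which limits cells with a UMI and not cells that express the gene. Coordinates are those of GENCODE vM21 on mm10, counted from 1.

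Free RNA was profiled in barcodes with 10 to 50 UMIs. Its share of the UMIs in cells was estimated from 3 antibody genes (Igkc, Igha and Jchain) in ILC-class cells with at most 10 such UMIs. This estimator was chosen after the data had been seen, in place of a median over more markers, which is given as an alternative.

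The ratio, its interval and the list percentile were tested on simulated counts drawn from the real means with 200 genes changed by known folds. The counts were independent Poisson draws, which the intervals assume, so coverage close to the nominal level was built in, for the random lists too. Extra variation between cells and shared regulation of list members were not simulated. For the ILC3 class (10701 genes) the intervals covered the true ratio in 95.9% of genes. All 32 genes with a 2-fold change that passed these limits had an interval that excluded 1. For the ILC2 class (10284 genes) coverage was 95.7%, with all 23 such genes outside 1. For the ILC1/NK class (7063 genes) coverage was 96.8% and 89.3% of 28 such genes were outside 1. In that class 45 of 2855 unchanged genes within these limits passed a ratio of 2 by their point value and 0 by their interval bound. Of 200 random lists, 5.5%, 5.5% and 5% fell outside the central 95% in these classes.

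The alternatives changed 1 choice at a time, except that the threshold of 2000 UMIs came with at least 500 genes and the limited cluster names with separate clustering. They covered the cell threshold, mitochondrial limit, doublets, clustering resolution, seed, variable genes, clustering of each library alone, class from per-cell marker scores, scaling, free RNA, thinning, low-count filters and the cells in the authors' table. Software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, leidenalg 0.10.2 and matplotlib 3.10.9.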

Results

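The data were 2 single-cell libraries of sorted IL7ra+ ILCs, 1 from the small intestine and 1 from the colon, each a pool of 8 mice. The small intestine library held 19745585 UMIs, of which 14464216 were in 5426 cells. The colon library held 25548284 UMIs, of which 20248083 were in 7262 cells. The median cell had 2537 UMIs and 1187 genes in the small intestine and 2548 UMIs and 1058 genes in the colon, or 704 and 632 genes after thinning. The median mitochondrial share was 2.52% and 2.72%. There were no replicates, and every interval covers counting error only.

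The first comparison asks which ILC classes each tissue held. ILC3-like cells, the class that makes interleukin 22, were 74.0% of the small intestine cells (4014 cells, interval 72.8 to 75.1%) and 14.6% of the colon cells (1062 cells, 13.8 to 15.5%). ILC2-like cells, the class that makes type 2 cytokines, were 16.4% (891 cells, 15.4 to 17.4%) and 58.7% (4264 cells, 57.6 to 59.9%). ILC1/NK-like cells were 1.90% (103 cells) and 10.0% (729 cells). A T-cell-like cluster led by Cd163l1, Trdc and Cd3e held 4.98% and 14.7%, although the sort was for ILCs. Clusters left without a name held 2.73% and 1.74%, most of them cluster 12 with 129 and 116 cells, led by Gzma, Ccl5 and Ly6c2.

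These shares are of cells that passed the IL7ra+ sort, and they depended on how clusters were named. The ILC3 share was 24.97% and 19.5% when each library was clustered on its own, 27.7% and 10.2% with a class per cell from marker scores, and 43.1% and 15.1% with a threshold of 500 UMIs. The ILC2 share was lower in the small intestine under every alternative. The ILC1/NK share was instead higher in the small intestine at Leiden resolution 2 (15.7% and 4.96%) and with marker scores (15.5% and 8.51%). At resolution 2 the small intestine ILC3 share was 60.1%, against 74.0% as reported, and its ILC2 share was 16.3%. In the colon the ILC3 share was 19.7%, against 14.6%. The ILC1/NK share thus rose where the ILC3 share fell and fell where it rose, so its turn was not separated from a change of cluster names.

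**Figure D1:**
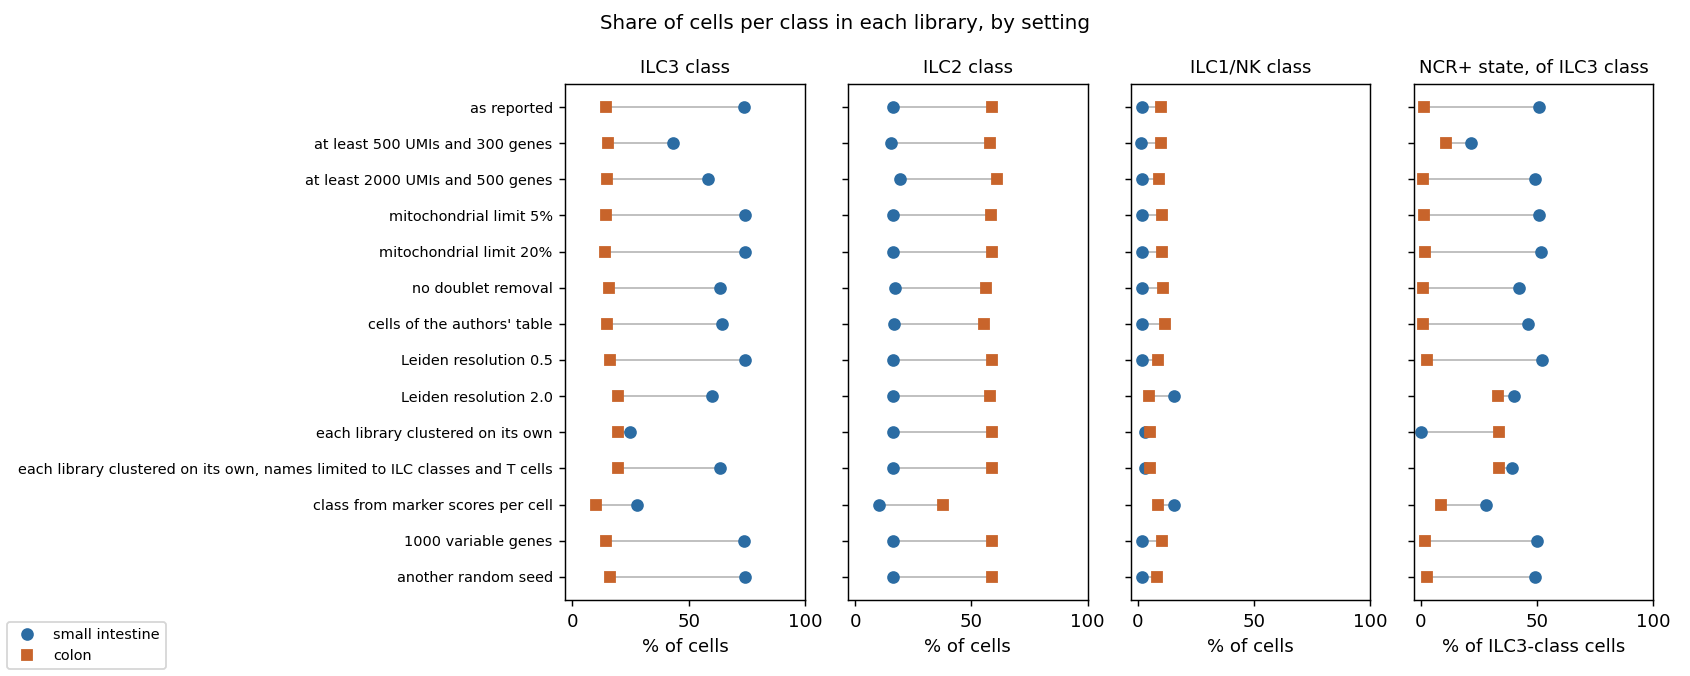
Percent of cells in each class (first 3 panels) and percent of ILC3-class cells in the NCR+ state (last panel), for the small intestine (circles) and colon (squares), by setting. The ILC2 share was 16.4% and 58.7% as reported and was higher in the colon in every setting, while the ILC3, ILC1/NK and NCR+ shares moved with the setting.

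Within the ILC3 class, 50.8% of small intestine cells (2040 of 4014) and 1.69% of colon cells (18 of 1062, interval 1.01 to 2.67%) were in NCR+ clusters, and the rest were in CCR6+ LTi-like clusters. This contrast rested on the clustering. At Leiden resolution 2, where the ILC3 class held 60.1% and 19.7% of cells, the NCR+ share was 40.4% and 33.3%. The NCR+ share was 21.6% and 10.8% with a threshold of 500 UMIs. With each library on its own it turned to 0% and 33.6%, where the only small intestine ILC3 cluster scored 1 for both states and was given the LTi-like name by a tie. With names then limited to ILC classes and T cells, an alternative added after seeing the data, it was 39.4% and 33.6%.

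The ILC3 class was compared next. Small intestine cells had more Ccr9, a chemokine receptor for homing to the small intestine, at 139 CPM against 1.11 CPM in the colon (125.5-fold, interval 48.9 to 461). They also had more Pcp4 (77.5-fold), Slc6a20a, an amino acid transporter (46.1-fold), Ffar2, a receptor for short-chain fatty acids (14.7-fold), Csf2, which encodes the cytokine GM-CSF (10.7-fold), Pram1 (11.9-fold), Eps8l3 (10.2-fold), Nt5e, the ectoenzyme CD73 (9.83-fold), the chemokine Ccl4 (7.47-fold) and Gimap7 (6.63-fold). Colon cells had more Ccr7, a receptor for homing to lymph nodes, at 752 CPM against 19.2 CPM (39.1-fold, interval 33.8 to 45.5). They also had more Tmem132c (17.7-fold), the polarity gene Pard3 (17.6-fold), the keratin Krt83 (12.9-fold), Impa2 (10.4-fold), Agpat4 (9.23-fold), Cd4 (8.29-fold), Bend4 (7.92-fold), the metalloprotease Adam8 (6.77-fold) and the inhibitory receptor Pdcd1 (5.85-fold). Ccr9 (ENSMUSG00000029530) lies on chromosome 9 at 123678439 to 123784330, and Ccr7 (ENSMUSG00000037944) on chromosome 11 at 99144196 to 99155077.

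Genes for presentation on MHC class II were higher in colon ILC3-class cells, where 8 of 10 measured members were at least 2-fold higher and 0 were in the small intestine. The median log2 ratio was −1.81, below all random lists (percentile 0). Cluster 11 is the NCR+ cluster with a heat-shock gene, Hspa1b, among its 10 leading genes. Without it the median was −1.67 (percentile 0), with a middle range from −1.95 to 0.03 that included 0. Colon cells of clusters 3 and 5 stayed in, with Hspa1a at 2005 and 4309 CPM, against 704 CPM in small intestine cells of cluster 11. Cd74, the invariant chain, was at 1780 CPM in the colon and 464 CPM in the small intestine, and H2-Aa at 615 and 142 CPM. Interferon-stimulated genes had a median of 0.79 (percentile 99.99), with 8 of 23 members at least 2-fold higher in the small intestine, such as Irf7 (3.27-fold) and Gbp2 (3.53-fold), while Ifit1 was 4.22-fold higher in the colon. Targets of NF-kB had a median of 0.39 (percentile 99.53), with 7 of 22 members at least 2-fold higher in the small intestine, among them Tnf (4.23-fold) and Nfkbid (3.28-fold). Cytotoxic effectors had a median of 1.39 (percentile 100), with 13 of 17 members higher in the small intestine, such as Ifng (5.47-fold), and Ccl5 4.34-fold higher in the colon. The tumour necrosis factor family member Tnfsf11 (RANKL) was at 629 CPM in the small intestine and 2018 CPM in the colon.

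The class was made of different clusters in each tissue, namely clusters 1, 3, 5 and 11 in the small intestine and cluster 6, with 85.4% of the class, in the colon. Ccr7, Cd4, Bend4, Pard3, Tmem132c, Pcp4, Slc6a20a, Ccr9, Pram1 and Eps8l3 also led such clusters, and the NCR+ state was nearly absent from the colon class. In the CCR6+ LTi-like state alone, Ccl4 turned to a log2 ratio of −0.57 and the cytotoxic list to −0.41, and without cluster 5, a low-Ccr6 cluster found almost only in the small intestine, the MHC class II list stood at −0.09 (percentile 12.3). In the LTi-like state the interferon list was at 0.13 (percentile 25.07) and the NF-kB list at 0.18 (percentile 85.84), each with a middle range that included 0, so these differences depended on which clusters were compared.

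Within the CCR6+ LTi-like state (1974 and 1044 cells), the small intestine had more Pcp4 (61.8-fold, interval 20.9 to 302, from 3 colon UMIs), Ffar2 (11.4-fold), Nt5e (7.84-fold), Hs6st2 (6.23-fold), the receptor tyrosine kinase Ret (6.06-fold), Rell1 (5.93-fold), the prostaglandin synthase Ptges (5.54-fold), the arginine-degrading enzyme Arg1 (4.78-fold), the purine receptor P2ry1 (4.69-fold) and the immediate early gene Nr4a1 (3.67-fold). The colon had more Lgals1, the lectin galectin 1 (18.1-fold), Ccr7 (17.8-fold), Impa2 (13.1-fold), Pard3 (9.86-fold), the chemokine receptor Ccr2 (9.75-fold), Tmem132c (9.25-fold), Krt83 (8.30-fold), the calcium-binding S100a6 (7.48-fold), Cd163l1 (6.72-fold) and the heat-shock gene Hspa1a (5.44-fold). T cell markers were also higher in these colon cells, Cd3e at 56.4 CPM against 4.56 CPM and Trdc at 135 CPM against 5.47 CPM, and the colon values were not separated from RNA of other classes. The state was mostly clusters 3 and 5 in the small intestine (1006 and 939 cells) and cluster 6 in the colon (907 cells). Rell1, P2ry1 and Hs6st2 led cluster 5, and Ccr7, Tmem132c and Pard3 led cluster 6. Without cluster 5, Ffar2 (10.4-fold), Ptges (6.71-fold), Ret (5.47-fold) and Rell1 (4.65-fold) stayed among the 10 genes named for the small intestine. Pcp4, Nt5e, Hs6st2, Arg1, P2ry1 and Nr4a1 did not, with log2 ratios there of 4.68 for Pcp4 and 2.25 for Nt5e. The MHC class II list had a median of −0.76 (percentile 0) with a middle range from −0.99 to 0.02, and 1 of 10 members was at least 2-fold higher in the colon. Vipr2, a receptor for vasoactive intestinal peptide, was at 44.7 CPM in the small intestine and 11.8 CPM in the colon. In cluster 3, the only ILC3 cluster with at least 50 cells in each library, Ccr7 had a log2 ratio of −1.44, Pcp4 of 0.96, Bend4 of 2.54 and Pdcd1 of 0.22. Hspa1a stood at 2005 CPM in the 104 colon cells of that cluster and 92.9 CPM in its 1006 small intestine cells.

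The ILC2 class was compared in the same way. Small intestine cells had more Cybb, a subunit of the phagocyte NADPH oxidase, at 67.9 CPM against 0.169 CPM (402-fold, interval 110 to 3343, from 2 colon UMIs). They had more Art2b, an ADP-ribosyltransferase (16.8-fold), Ccr9 (8.34-fold), the Notch regulator Dtx1 (6.21-fold), the protease Lgmn (6.01-fold), the receptor Cd160 (5.50-fold), Atp8a2 (4.85-fold) and the transglutaminase Tgm2 (4.63-fold). Colon cells had more Lgals1 at 661 CPM against 28.1 CPM (23.5-fold, interval 18.9 to 29.8), and more of the calcium-binding genes S100a6 (19.8-fold) and S100a4 (12.5-fold). They also had more Ccr2 (11.4-fold), the actin-capping gene Capg (10.3-fold), Ctla2a (8.38-fold), Anxa1 (8.32-fold), Ramp1, a co-receptor for the neuropeptide CGRP (6.86-fold), the nuclear lamin Lmna (6.72-fold) and Crip1 (5.24-fold). Lgals1 (ENSMUSG00000068220) lies on chromosome 15 at 78926725 to 78930465 and Cybb (ENSMUSG00000015340) on chromosome X at 9435252 to 9487771.

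Interferon-stimulated genes were higher in small intestine ILC2-class cells (median log2 ratio 0.80, percentile 100), with 9 of 22 measured members at least 2-fold higher and 0 in the colon, among them Gbp2 (3.06-fold) and Igtp (2.69-fold). The list of type 2 cytokines and effectors had a median of 0.44 (percentile 99.97) but went both ways. The neuropeptide gene Calca was 2.53-fold higher, Il4 2.01-fold and Tph1, the first enzyme of serotonin synthesis, 12.6-fold higher in the small intestine, while Il5 was 2.26-fold higher in the colon. In the retinoic acid list 6 of 10 members were at least 2-fold higher in the small intestine (median 1.02, percentile 100), among them Dhrs3 (14.0-fold) and Ccr9, with a middle range that reached −0.31. Glycolysis genes had a median of −0.16 (percentile 1.07) with 1 of 23 members at least 2-fold apart.

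The class was held by cluster 8 in the small intestine, with 90.0% of it, and by clusters 0, 4, 7 and 10 in the colon, and Cybb, Art2b, Atp8a2, Lgmn and Ctla2a also led such clusters. Each of these clusters was mostly of 1 library, so they may be that library and not a cell type. The genes listed first above, from Cybb to Tgm2 and from Lgals1 to Crip1, kept a ratio of at least 2 under the alternatives of scaling, threshold and class that were run.

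**Figure D2:**
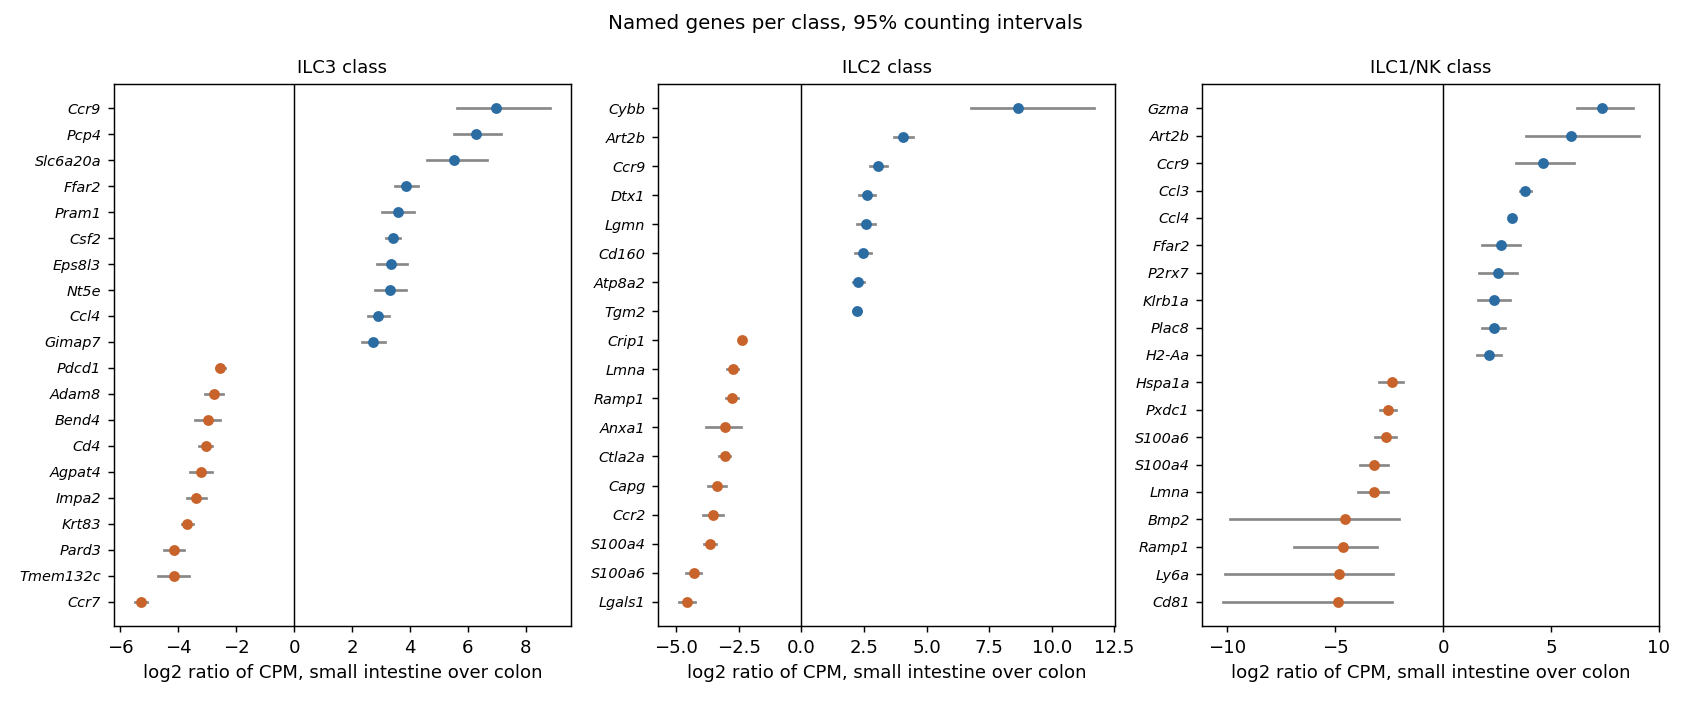
Log2 ratio of CPM, small intestine over colon, for genes named in the text for each class, with 95% counting intervals as lines. Ccr9 was higher in the small intestine in all 3 classes, by 125.5-fold, 8.34-fold and 24.9-fold; Ccr7 in the ILC1/NK class is not drawn because the small intestine had 0 UMIs.

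The ILC1/NK class held 103 small intestine and 729 colon cells, all in cluster 9. Small intestine cells had more Gzma, the protease granzyme A, at 527 CPM against 3.23 CPM (163-fold, interval 73.1 to 452). They had more Art2b (60.3-fold, interval 14.4 to 536, from 2 colon UMIs), Ccr9 (24.9-fold), the chemokines Ccl3 (14.1-fold) and Ccl4 (9.30-fold), Ffar2 (6.43-fold), the purine receptor P2rx7 (5.90-fold), Klrb1a (5.15-fold), Plac8 (5.10-fold) and H2-Aa (4.41-fold). Colon cells had more Cd81 (29.4-fold, interval 5.22 to 1167), Ly6a (27.9-fold, interval 4.95 to 1108) and the growth factor Bmp2 (23.4-fold, interval 4.14 to 931), each from 1 small intestine UMI. Ramp1 was 24.8-fold higher from 3 small intestine UMIs, with an interval of 8.45 to 121. Colon cells also had more Lmna (9.28-fold), S100a4 (9.03-fold), S100a6 (6.25-fold), Pxdc1 (5.82-fold) and Hspa1a (5.199-fold), and Ccr7 was at least 5.57-fold higher. The cytotoxic list had a median of 0.78 (percentile 100) with 5 of 17 members at least 2-fold higher in the small intestine and 0 in the colon, such as Nkg7 (2.29-fold). Clock genes had a median of −0.95 (percentile 0) with 8 of 16 members higher in the colon, with a middle range that reached 0.09.

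Il22 stood at 1392 CPM over the 729 colon cells of this class, of which 374 were in NCR+ clusters at Leiden resolution 2. In the highest-scoring ILC1/NK cluster at that resolution (89 and 355 cells, chosen after seeing the data) Gzma was 89.8-fold, Ccl4 5.23-fold and Ccl3 7.84-fold higher in the small intestine, S100a4 was 14.8-fold higher in the colon, the cytotoxic list stood at 0.20 and the clock list at 0.16 (percentile 83.58). With a class per cell from marker scores, the log2 ratio was −0.14 for Klrb1a, −0.87 for H2-Aa and −0.05 for the cytotoxic list.

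**Figure D3:**
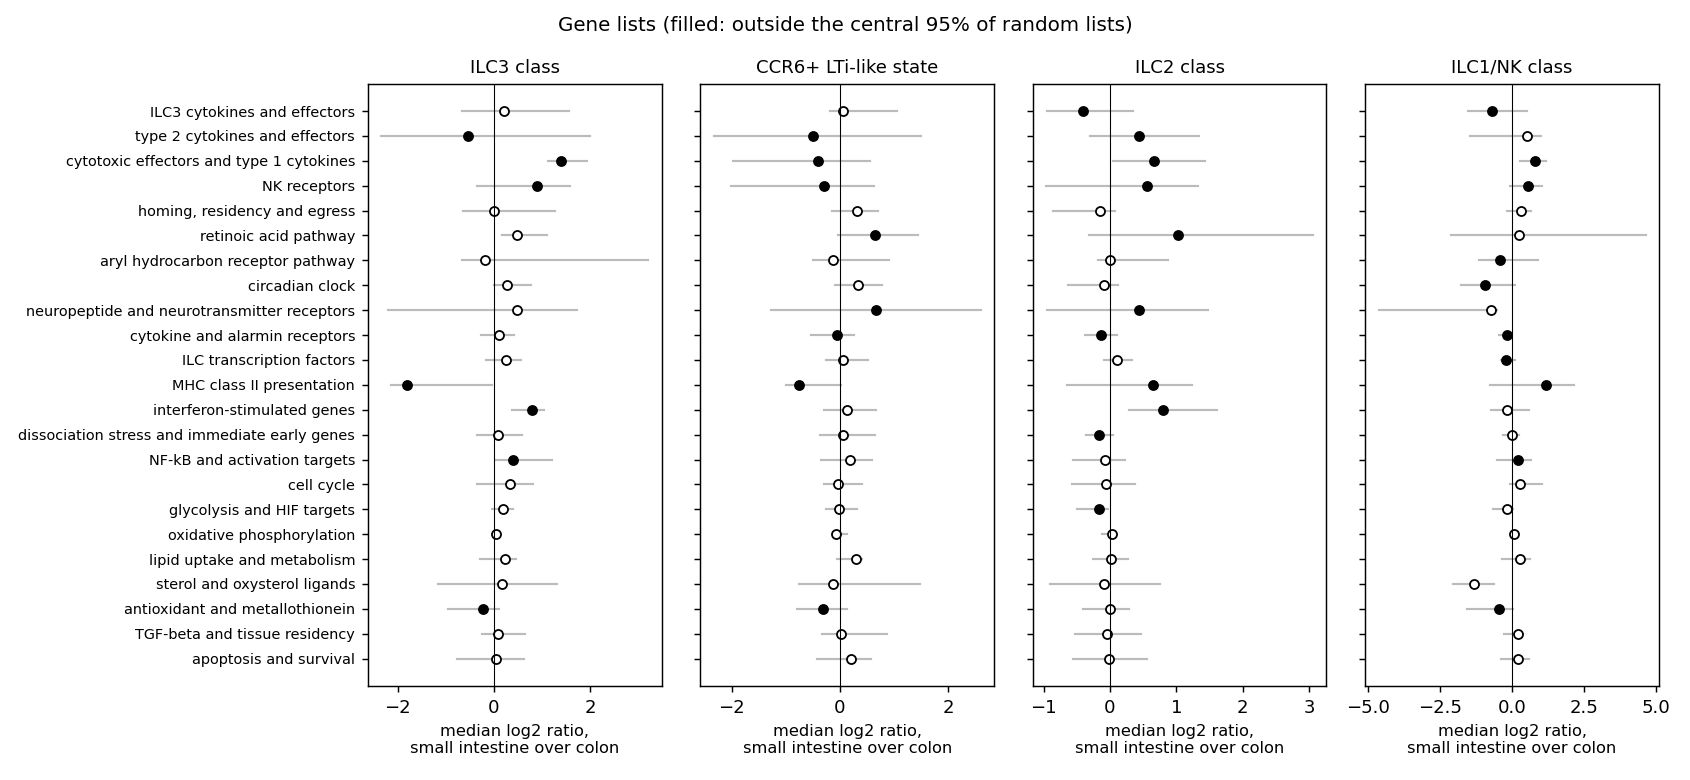
Median log2 ratio, small intestine over colon, of the measured members of 23 gene lists in each population, with lines for the order-statistic interval of the median. Filled points lie outside the central 95% of 10000 random lists; the MHC class II list stood at −1.81 in the ILC3 class and 1.18 in the ILC1/NK class.

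Over all cells, class makeup and levels within a class add up. Of the 23 gene lists, 10 lay outside the central 95% of random lists over all cells, 7 in the ILC3 class, 11 in the ILC2 class and 10 in the ILC1/NK class. The small intestine had more Pcp4 (102-fold), Slc6a20a (88.0-fold), Gzma (61.3-fold), Eps8l3 (23.2-fold), Pram1 (13.7-fold), Ccr9 (12.7-fold), Hs6st2 (10.8-fold), Ffar2 (8.72-fold), Ppp1r3b (6.73-fold) and Car2, a carbonic anhydrase (6.42-fold). The colon had more Ctla2a (21.3-fold), Rab27b (9.41-fold), the interleukin 33 receptor Il1rl1 (8.24-fold), Il5 (6.76-fold), Ccr7 (6.11-fold), Lmna (6.03-fold), Krt83 (5.74-fold), S100a6 (5.26-fold), Lpcat2 (5.19-fold) and Lgals1 (4.36-fold). Gzma stood at 2310 CPM in the 129 small intestine cells of unnamed cluster 12, which held most of its 919 small intestine UMIs. The median gene stood at a log2 ratio of 0.21 over all cells, 0.21 in the ILC3 class and 0.20 in the LTi-like state. A median-ratio size factor moved all ratios by 0.22, 0.12 and 0.12 there.

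Shares of cells with a UMI were compared after thinning, with median depths before thinning of 2441 and 2770 UMIs in the ILC3 class and 3064 and 2623 UMIs in the ILC2 class. Il22 was seen in 70.2% of small intestine and 82.4% of colon ILC3-class cells (82.1% and 88.5% unthinned), against 28.5% and 13.4% of ILC2-class cells as background (55.7% and 26.1% unthinned). Il17f was seen in 5.80% and 10.9% of ILC3-class cells (8.27% and 17.4% unthinned), with 0.449% and 0.188% in the ILC2 class. Ifng was seen in 4.66% and 0.659% (7.32% and 2.07% unthinned), with 0.337% and 0.375% in the ILC2 class. With a threshold of 500 UMIs both ILC3-class differences, small intestine minus colon, turned, to 0.311 points for Il17f and −0.152 points for Ifng. In the LTi-like state the thinned shares were 79.0% and 83.3% for Il22 (86.7% and 89.5% unthinned), 10.5% and 11.1% for Il17f and 0.557% and 0.575% for Ifng, and the intervals of the differences for Il17f and Ifng included 0. In the NCR+ state Il22 was seen in 61.7% of small intestine cells and in 5 of the 18 colon cells (27.8%). Within each LTi-like cluster the Il22 level was higher in the small intestine, unlike the shares over the state. It was 7148 against 2348 CPM in cluster 3 (1006 and 104 cells). It was 9299 against 5000 CPM in cluster 5 (33 colon cells) and 15051 against 9705 CPM in cluster 6 (29 small intestine cells). In NCR+ clusters 1 and 11, with 10 and 8 colon cells, it was 4620 against 8072 CPM and 782 against 205 CPM. Ccr9 was seen in 12.2% of small intestine ILC3-class cells and in 0 of 1062 colon cells, which allows a share of cells with a UMI at this thinned depth of up to 0.282% (21.6% and 0.377% unthinned). In the LTi-like state it was seen in 2.03% of small intestine cells and in 0 of 1044 colon cells (a limit of 0.287% on cells with a UMI), and in the NCR+ state in 22.1% of small intestine cells. In the ILC2 class Il5 was seen in 9.88% and 16.5% (18.2% and 26.4% unthinned), with 0.174% and 1.41% in the ILC3 class. Areg, which encodes amphiregulin, was seen in 33.8% and 28.1% of ILC2-class cells (51.2% and 40.1% unthinned), with 6.70% and 6.21% in the ILC3 class. Vipr2 was seen in 4.81% and 1.63% of LTi-like cells (9.02% and 3.74% unthinned), against 0 of 270 (a limit of 1.11%) and 3 of 1071 T-cell-like cells (0.280%), whose median depths were 2433 and 2204 UMIs. Vipr1 was seen in 0 of 4014 and 0 of 1062 ILC3-class cells, with limits of 0.0747% and 0.282% on cells with a UMI.

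Comparing classes within a library, 6 of 19 clock genes were at least 2-fold higher in ILC3-class than in ILC2-class cells of both libraries. These were Nr1d1, which encodes the repressor REV-ERBα (8.68-fold in the small intestine and 2.28-fold in the colon), Usp2 (3.64-fold and 8.26-fold), Nfil3 (2.56-fold and 2.20-fold), Bhlhe40, Csnk1e and Cry2. The clock output gene Hlf was higher in ILC2-class cells (4.63-fold and 5.82-fold). Of 8 neuropeptide and neurotransmitter receptor genes, Ret was higher in the ILC2 class of both libraries (2.42-fold and 2.39-fold) and Adra2a in the ILC3 class (14.7-fold and 31.7-fold, from 1 and 3 ILC2-class UMIs). Of 9 MHC class II genes, 6 were higher in the ILC3 class of both libraries, such as H2-Aa (9.72-fold and 84.7-fold). In the small intestine this did not hold for each ILC3 cluster. Cd74 was at 1813 CPM in cluster 3 but at 17.9, 69.1 and 14.1 CPM in clusters 1, 5 and 11, against 106 CPM in the ILC2 class. H2-Aa was at 529 CPM in cluster 3 and at 9.52, 21.2 and 5.96 CPM in those clusters, against 14.6 CPM in the ILC2 class. Among homing genes, Ccr4 was higher in the ILC2 class (94.2-fold and 25.4-fold) and 6 others, with Cxcr3 (13.6-fold and 6.65-fold) and Cxcr4 (6.89-fold and 4.66-fold), in the ILC3 class.

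Free RNA made up an estimated 5.37% of UMIs in small intestine cells and 8.22% in colon cells, and 4.90% and 4.72% when estimated from Il22 in the ILC2 class. Igkc, an antibody gene, stood at 4225 CPM over all small intestine cells and 1455 CPM over colon cells, most of it from the 19 and 10 cells of unnamed cluster 13 (235938 and 222335 CPM). Igkc was at 321 and 52.4 CPM in the ILC3 class and at 144 and 175 CPM in the ILC2 class. Il22 was at 5806 CPM in small intestine and 2453 CPM in colon empty droplets. The epithelial markers together were at 66.6 CPM and 284 CPM in empty droplets and at 13.5 CPM and 40.0 CPM in ILC-class cells.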

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

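All tests of explanations in this part were chosen after the results they concern had been seen.

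Genes were taken that had at least 50 CPM in the higher library in each of the ILC3 and ILC2 classes. Of these, 5 stood at least 2-fold apart between the tissues in opposite directions in the 2 classes, with both counting intervals past 2. The difference between the classes was not tested, since there was 1 library per tissue. The transglutaminase gene Tgm2 had a log2 ratio, small intestine over colon, of −1.31 in the ILC3 class and 2.21 in the ILC2 class. The chemokine Cxcl10 stood at −1.47 and 1.33, and the invariant chain Cd74 at −1.94 and 1.57. By ILC3 cluster, Cd74 was at 1813 CPM in the small intestine and 1758 CPM in the colon in cluster 3. It was at 3203 CPM (29 cells) and 1834 CPM in cluster 6, so the difference over the class was not seen in clusters 3 and 6. It was higher in the colon in cluster 5, at 69.1 CPM and 265 CPM (33 cells). The same held in cluster 1, at 17.9 CPM and 256 CPM (10 cells), and in cluster 11, at 14.1 CPM and 154 CPM (8 cells). The activation and retention marker Cd69 stood at 1.47 in the ILC3 class and −1.44 in the ILC2 class, and the stress-response gene Gadd45b at 1.23 and −1.21.

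Some cells were in none of the ILC classes, and the gene comparisons within a class did not use them. T-cell-like cells made up 4.98% of small intestine and 14.7% of colon cells after a sort for ILCs. Cells of unnamed clusters made up 2.73% and 1.74%, and lymphatic-endothelial-like cells led by Mmrn1 and Lyve1 made up 0.138% of colon cells (10 cells).

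Few colon ILC3-class cells were in NCR+ clusters, 18 of 1062. At Leiden resolution 2 the colon had 477 cells in NCR+ clusters, of which 78.4% had been in the ILC1/NK cluster, so the low share may come from the clustering resolution. Doublets of ILC1/NK and ILC3 cells would hold more UMIs, but the median UMI total of those cells was 0.9996 of that of all colon cells, which argues against doublets as their source. In the small intestine fewer cells were in NCR+ clusters at that resolution, 1316 against 2040, and the ILC1/NK share was 15.7% against 1.90%. The closer NCR+ shares of the tissues, 40.4% and 33.3%, thus also reflect the small intestine side. Clusters 1 and 11 had been named ILC3 by scores of 0.386 and 0.394, against 0.353 and 0.334 for ILC1/NK. The tissue itself remains an untested explanation for any difference that is left.

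Hba-a1, an alpha-globin gene, was among the leading genes of the small intestine ILC2 cluster, at 97.7 CPM in the small intestine ILC2 class and 21.6 CPM in the colon ILC2 class. RNA of red blood cells would reach all classes of a library, but the ILC3 class, at 0.789 and 1.66 CPM, had at most 7.69% of the ILC2 level, which argues against red-cell RNA. The beta-globin genes Hbb-bs and Hbb-bt had 0 UMIs over all barcodes as read here, empty droplets included, and were given no weight. Reads shared with the near-identical Hba-a2, which had 14 and 8 UMIs in the ILC2 classes against 275 and 256 for Hba-a1, leave open which alpha-globin gene they came from, and no biological explanation was tested.

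Il22 UMIs were found in ILC2-class cells, at 285 CPM in the small intestine and 116 CPM in the colon. Free RNA at the antibody-based share would give 312 and 202 CPM, and the measured levels were 91.2% and 57.4% of these. Free RNA cannot give more than the measured level, so the antibody-based share was too high for Il22 in the colon. It was 8.22% there, against 4.72% from Il22. The subtraction used for named genes rests on the antibody-based share and may take too much from colon cells. Areg, which ILC2 express, stood at 4860% and 1685% of its level from free RNA. Areg was among the markers that named the ILC2 class, and Il22 among those that named the ILC3 class. Areg therefore cannot show whether the measure for Il22 could have come out otherwise. Free RNA is a candidate source for all Il22 seen in this class, and low expression beneath it cannot be excluded.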

How the results depend on the processing

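No paired analysis was possible because there was 1 library per tissue, and no test was run under any alternative. Across all results and alternatives, 2616 values stayed within their counting interval or within 1.5 times the reported count, 381 moved past it in the same direction or without a called direction, and 17 reversed. The NCR+ and ILC1/NK clusters at resolution 2 as populations and the LTi-like state without its Ccr6-low cluster were chosen after seeing the data. So were the ILC3 class without cluster 11, the limited names and the median-based free RNA share. Causes were not tested except where said.

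The ILC3 share difference, 59.4 percentage points as reported, was 27.98 with at least 500 UMIs, 43.4 with at least 2000 UMIs and 500 genes, 47.7 without doublet removal, 49.3 in the authors' cells, 40.4 at Leiden resolution 2, 5.43 with each library on its own, 43.8 with names then limited to ILC classes and T cells, 17.5 with marker scores and 57.9 with another seed. With each library on its own, limiting the names to ILC classes and T cells raised the small intestine ILC3 share from 24.97% to 63.3%. The lower value thus came from naming, and which clusters lost the ILC3 name was not resolved here. In the joint clustering, dendritic cell was the second-scoring name of LTi-like clusters 3, 5 and 6. The ILC2 difference, −42.3, was −39.1 without doublet removal, −39.02 in the authors' cells and −27.8 with marker scores. The ILC1/NK difference, −8.14, was −9.98 in the authors' cells, −6.80 at resolution 0.5, 10.8 at resolution 2, −2.11 with each library on its own, under both sets of names, 6.95 with marker scores and −6.67 with another seed. The NCR+ difference, 49.1, was 10.7 with at least 500 UMIs, 41.3 without doublet removal, 45.3 in the authors' cells, 7.06 at resolution 2, −33.6 with each library on its own, 5.83 with limited names, 19.4 with marker scores and 46.5 with another seed. The −33.6 came from naming: the small intestine then had 1 ILC3 cluster, which scored 1 for both states, and the same 1355 cells were NCR+ with limited names.

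Of the 10 lists outside the central 95% over all cells, 6 stayed outside on the same side with means of per-cell values. Of the 7 in the ILC3 class, those that did were 3 in the LTi-like state, 3 in cluster 3, 4 with at least 500 UMIs, 2 in NCR+ clusters at resolution 2 and 1 in the LTi-like state without its Ccr6-low cluster. Of the 10 in the ILC1/NK class, they were 6 after thinning, 3 with each library on its own under both sets of names, and 1 with marker scores. Of the 11 share differences in the 3 ILC classes whose interval excluded 0, none turned with marker scores, and 7 still had an interval that excluded 0.

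Among single genes and lists, the ILC3-class log2 ratio of Ccl4 was −0.57 in the LTi-like state, −0.65 there without the Ccr6-low cluster and −0.33 with at least 500 UMIs, and the cytotoxic list stood at −0.41, −0.65 and −0.16. In cluster 3 Bend4 was at 2.54 and Pdcd1 at 0.22. With marker scores the ILC1/NK-class ratios of Klrb1a and H2-Aa were −0.14 and −0.87, and the cytotoxic list was at −0.0481. The Vipr2 share difference in the ILC2 class was −0.0101 points when thinned to 500 UMIs, and those of Il17f and Ifng in the ILC3 class were 0.311 and −0.152 points with at least 500 UMIs. The free RNA share was 5.4% in the colon from barcodes with 1 to 10 UMIs and 8.94% in the small intestine from the median over B cell, plasma cell and epithelial markers. Depth limits the ILC1/NK class, where the 103 small intestine cells held 276928 UMIs and several named genes rest on 1 to 3 UMIs in a tissue.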

Other observations

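The NCR+ clusters at Leiden resolution 2, a grouping chosen after seeing the data, held 1316 small intestine and 477 colon cells and had like levels of Ncr1 (348 and 362 CPM) and Il22 (4233 and 4447 CPM). Small intestine cells had more Ccr9 (33.5-fold), Pcp4 (32.4-fold), Ccl4 (17.4-fold), Ffar2 (13.2-fold), Rell1 (11.2-fold) and Csf2 (712 against 162 CPM). Colon cells had more Ccr7 (91.4-fold), Cd74 (24.4-fold), Krt83 (19.6-fold), Bmp2 (18.1-fold), Lmna (11.7-fold) and Klrd1 (12.7-fold). Ifng was at 58.4 CPM in the small intestine and 116 CPM in the colon. Of the 477 colon cells, 83 (17.4%) came from LTi-like cluster 6, whose colon cells had Ccr7 at 829 CPM and Cd74 at 1834 CPM, so the Ccr7, Cd74 and MHC class II values were not separated from that cluster. Another 374 (78.4%) came from the ILC1/NK cluster, whose colon cells had Klrd1 at 420 CPM, Lmna at 636 CPM and Bmp2 at 84.6 CPM, so the values of these genes were not separated from that origin. In the MHC class II list 6 of 8 measured members were at least 2-fold higher in the colon, with a median log2 ratio of −3.14 and a middle range from −4.61 to 1.97.

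The T-cell-like cluster held Il17a in 4.81% of 270 small intestine cells and 3.92% of 1071 colon cells after thinning, against 0.337% and 0.235% of ILC2-class cells. Its Trdc level, the constant region of the T cell receptor delta chain, was 1924 CPM in the small intestine and 2221 CPM in the colon. Unnamed cluster 12 had Gzma at 2310 CPM in the small intestine and 46.1 CPM in the colon, and Trdc at 1662 and 1097 CPM.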
